A study of Saccharomyces cerevisiae with 11 samples.

How the data were processed

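RNA of the budding yeast Saccharomyces cerevisiae was measured on 11 Affymetrix YG-S98 arrays, which carry 9335 probe sets for the yeast genome. The labels name the wild-type strain BY4741, a haploid laboratory strain of mating type a, and the mutant strain, given as fks1 strain 5251 in the labels and called fks1 here, carried a mutation of FKS1, the gene of the main catalytic subunit of the enzyme that makes the cell wall glucan. Glucosamine is an amino sugar that cells can phosphorylate and use to make the sugar nucleotide from which chitin is built. Wild-type cells were untreated (3 arrays), given 15 mM glucosamine for the last 2 h of growth (3 arrays), or grown with 15 mM glucosamine both overnight and after dilution (3 arrays), which is called continuous here. The fks1 cells were untreated (1 array) or given 15 mM glucosamine for 2 h (1 array). Per the labels' protocols, cultures grew in YPD, a rich glucose medium, to an optical density of 1.6 to 1.8 at harvest, RNA was extracted with hot phenol, and biotin-labelled cRNA was hybridised to the arrays. The labels number the replicates and do not say whether the numbers mark separate cultures, so every p-value measures a spread between arrays that may be partly or wholly technical.

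The deposited values are signals, 1 per probe set and array, which the submitters analysed and normalised with GeneChip Analysis Suite, per the labels' protocols; the version and the settings are not given in the sources used here. The 2% trimmed mean of the arrays ran from 500.4 to 500.5, a ratio of 1.0002 between the highest and the lowest, so the values were used as deposited under a rule fixed before the data were examined (rescaling above a ratio of 1.1). A common mean on every array removes any difference in total RNA per cell between groups. The median signal per array ran from 122.7 to 150.0, and 76.7% to 81.3% of the probe sets read above 25.5, the 95th percentile of 19 background control probe sets. The number of arrays limits the precision, and low signals carry more of the array background.

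Signals under a floor of 7.7, the 10th percentile of all values, were set to that floor and then transformed to log2. The 60 control probe sets were left out, and 8616 of the remaining 9275 probe sets were tested because they lay above the floor on at least 3 of the 9 wild-type arrays, which left 659 untested. Genes were named from the platform's gene table, with symbols updated through a RefSeq gene table of assembly R64. A single symbol was found for 6504 probe sets, all of them matched in that table, while 328 matched several genes and 2443 had no name. These cover 5656 genes, of which 5568 were tested. Probe sets that match several genes or none were counted and not named, and identifiers that end in _f_at or _s_at mark probe sets that can bind transcripts of related genes. Genome coordinates are not given in the sources used here. Measurements on such arrays cannot separate near-identical copies, which concerns transposon families and paired genes such as HXT6 and HXT7.

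The 9 wild-type arrays were fitted together in limma 3.58.1 (R 4.3.3), with moderated statistics and a trend of the variance with the mean, for 2 h against untreated, continuous against untreated and continuous against 2 h. Benjamini-Hochberg adjustment was made over the 8616 probe sets of each comparison, with a threshold of 0.05, and all tests were two-sided. Means are given with SD over 3 arrays, and log2 differences with the standard error of limma's fit. There were 28 gene lists, fixed before the data were examined, of 654 genes, of which 633 had a probe set. The 26 lists with at least 5 tested members were tested with camera, which asks whether the genes of a list move more to one side than other genes do, at its preset correlation of 0.01 between genes. Each call was tried again with the correlation estimated from the data and with fry, which asks whether the genes of a list move on balance in 1 direction. Within a list, adjustment was also made over the list alone.

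For fks1, a probe set was counted where it differed at least 2-fold in the same direction from each of the 3 untreated wild-type arrays. A fit of all 11 arrays that borrows the spread of the wild-type groups gave p-values for fks1 against untreated wild type and for the difference of the 2 h responses of the strains. Each list's median was set among 10000 random lists of the same size matched on mean signal. Random lists leave out the correlation between the genes of a list, so the medians were also set beside those of single wild-type arrays, a comparison added after the data were seen. Folds of fks1 with a signal under the control percentile are given as bounds, with that percentile in place of lower signals. Responses that share the untreated arrays were compared with 100 simulations in which no group changed, with independent arrays and, added after the data were seen, with untreated and 2 h arrays correlated at the mean r of 0.481 of their numbers.

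Named genes followed a rule fixed before the data were examined: the 10 largest rises and 10 largest falls that passed the test without overlap between the arrays of the groups and above the floor on every array of the higher group, up to 4 passing members per list by p or up to 2 largest changes where none passed, and in every case FKS1, GSC2, the hexosamine and chitin genes and the marker genes of the strain. RIB4 and HPF1 are called in more than 1 comparison, and other genes named outside the rule (ARO9 and ARO10 in continuous against untreated, members that passed over a list alone, members of the paired fit) were chosen after their values were seen. Markers of other cells or states that a culture might hold were among the lists: the 4 genes of mating type alpha had median log2 differences of 0.20 at 2 h and 0.13 in continuous glucosamine, and the 14 tested genes of stationary phase had -0.16 and 0.02, with 0 of either list called by limma without pairs (1 of the stationary phase genes, HSP30, was called, lower, in the paired fit of the 2 h arrays) and, for the second list, camera adjusted p of 0.903 and 0.625.

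The replicate numbers were checked for pairing by the correlation of the arrays' deviations from their group means, and were taken to pair groups where every number gave an r over 0.1. Arrays of the same number went together in untreated and 2 h wild type (r across probe sets of 0.356, 0.570 and 0.517 for numbers 1, 2 and 3), while untreated and continuous (-0.236 to -0.0062) and 2 h and continuous arrays (-0.204 to -0.0365) did not. The pairing comes from these values and not from the labels. Paired values, from a fit of the 6 arrays with the number as a block, are therefore given for 2 h glucosamine where they differ.

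The steps were tested on simulated data with the real means and spread, in 20 simulations with 200 changed probe sets each. For 2 h against untreated, 7.71% of the changes of 1.5-fold, 41.2% of those of 2-fold and 88.1% of those of 4-fold were recovered, with 4.17% false calls. For continuous against untreated these were 7.71%, 42.1% and 88.5%, with 4.81% false calls. The rule for fks1 recovered 4.86%, 25.4% and 92.2% with 53.3% false calls, and its fit with the pooled spread 1.39%, 14.1% and 63.3% with 5.01%. A planted list of 25 genes shifted by 0.5 log2 units was called in 20 of 20 simulations and an unchanged one in 0. Probe sets and arrays were drawn independently, without correlation between the genes of a list and without pairs of arrays. The shares of false calls hold for such arrays only. They cannot show how often camera calls an unchanged list in these data, where the estimated correlation reached 0.773 in the respiratory chain list. Alternatives changed the scaling, the floor, the filter, the choice of probe sets, the variance model, the samples in the fit and the pairing, and each array was left out in turn. Further alternatives were added after the data were seen: a floor at the control percentile, a filter on a mean signal of 100, the removal of family probe sets or of unnamed and shared ones, the removal of the untreated and 2 h arrays numbered 2, and the paired fit of 6 arrays.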

Results

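The arrays asked how yeast transcripts respond when cells receive glucosamine, a precursor of the cell wall polymer chitin, and whether fks1 cells, whose wall glucan synthesis is impaired, differ from wild type in the same genes. There were 3 untreated wild-type arrays, 3 after 2 h of 15 mM glucosamine, 3 of continuous growth in it, and 1 array each of untreated and 2 h treated fks1 cells. Each array held 1 signal per probe set with a trimmed mean of 500.4 to 500.5. The fks1 values have no replicates.

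After 2 h of glucosamine, RIB4, the gene of lumazine synthase in riboflavin synthesis, rose 1.71-fold, from a signal of 2579 ± 164 to 4410 ± 154 (SD, n = 3; log2 0.78, SE 0.10, limma adjusted p = 0.0411). It was the 1 named gene that passed. The other 2 calls were unnamed probe sets that fell (log2 -2.34, SE 0.23, and -2.20, SE 0.27). None of the 12 genes of hexosamine and chitin synthesis passed, by limma over all probe sets or adjusted over the list alone, and 2 had an unadjusted p under 0.05. GFA1, the first enzyme of hexosamine synthesis, measured 1.25-fold (log2 0.32, SE 0.14, adjusted p = 0.810) and PCM1, the phosphoacetylglucosamine mutase, 1.24-fold (log2 0.31, SE 0.12, adjusted p = 0.754). The chitin synthase genes CHS1, CHS2 and CHS3 had log2 differences of 0.06, 0.12 and 0.08.

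The clearest shift of a list after 2 h was in the 24 tested cell wall stress genes, most of them targets of the cell integrity pathway. All 24 had a positive log2 difference, with a median of 0.42, 0 passed over all probe sets by limma (522 of 8616 had an unadjusted p under 0.05 without pairs, against 430.8 by chance), and 5 passed adjusted over the list alone. These 5 were KDX1 (log2 1.59, SE 0.28), SRL3 (1.68, SE 0.42), PRM5 (0.96), TOH1 (0.75) and CRH1, a chitin transglycosylase (0.55, SE 0.11). The list was higher by camera (adjusted p = 6.86e-17), a call lost with the correlation estimated (adjusted p = 0.591 with an estimated correlation). The mean of the list on the 2 h arrays numbered 1, 2 and 3 lay 0.77, 0.57 and 0.22 above that of untreated cells. Other lists higher by camera were glycolysis and fermentation (14 of 17 positive, median 0.12, adjusted p = 0.000131) and glucan synthesis and remodelling (17 of 24, median 0.09, adjusted p = 0.00251). HXK2 of the first measured 1.26-fold and PGI1 1.20-fold, and CRH1 was the 1 member of the second past adjusted over the list alone. Also higher were the mating type a and pheromone genes (11 of 18, median 0.09, adjusted p = 0.0208) and the hexosamine and chitin list (8 of 12, median 0.07, adjusted p = 0.0456). So were the G2/M list (10 of 14, median 0.12, adjusted p = 0.0406) and the nitrogen catabolite list (13 of 23, median 0.03, adjusted p = 0.0456), the last with CAR1, the arginase, as the 1 member past adjusted over the list alone (log2 0.66). Ribosome biogenesis (42 of 50 negative, median -0.22, adjusted p = 0.0208), the phosphate regulon (12 of 16, median -0.24, adjusted p = 0.0284) and cell separation (10 of 11, median -0.20, adjusted p = 0.0284) were lower, with 0 members past adjusted over each list alone. PHO5, the secreted acid phosphatase, measured -1.53 (SE 0.41, adjusted p = 0.572) and the ribosomal protein gene RPL7B -1.55 (SE 0.46, adjusted p = 0.641). All 10 of these camera calls were lost with an estimated correlation, where the smallest adjusted p was 0.591, and fry called 0 (smallest adjusted p = 0.585). Without untreated array 1 or 2 camera called 5 or 6 lists, and without 2 h array 1 the ribosome biogenesis genes turned to higher with adjusted p = 0.185. The hexosamine and chitin call and the nitrogen catabolite call were each lost in 11 of 24 alternatives, 7 and 6 of these with 1 array left out.

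The paired fit of the 6 arrays called 17 probe sets at 2 h in place of 3, with all 3 kept, of which 4 rose and 13 fell. By limma 1107 probe sets had an unadjusted p under 0.05 in that fit, against 522 without pairs. Among them SRL3 (log2 1.68, SE 0.19), DPI8 (0.95, SE 0.13) and RIB4 rose, while PHO5 (-1.53, SE 0.13), PHM6 (-1.28, SE 0.14), the zinc transporter gene ZRT1 (-1.69, SE 0.17), RPL7B (-1.55, SE 0.18), HSP30 (-1.03, SE 0.13) and SNR72 (-1.03, SE 0.14) fell. HSP30, a stationary phase gene, read 1182 ± 1411 (SD, n = 3) in untreated cells, and its unpaired difference was 0.0046 without untreated array 2. In that fit the hexosamine and chitin list no longer passed (adjusted p = 0.0718), the general stress list did, lower (adjusted p = 0.00139), and with an estimated correlation 0 lists passed (smallest adjusted p = 0.679). The unpaired count of 3 fell to 0 without untreated array 1, 2 or 3, without 2 h array 1 or 3 or without continuous array 3, and to 1 without 2 h array 2 or continuous array 1 or 2. RIB4 had a log2 difference of 0.72 to 0.87 and adjusted p of 0.0229 to 0.502 over 28 alternatives and passed in 7.

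**Figure D1:**
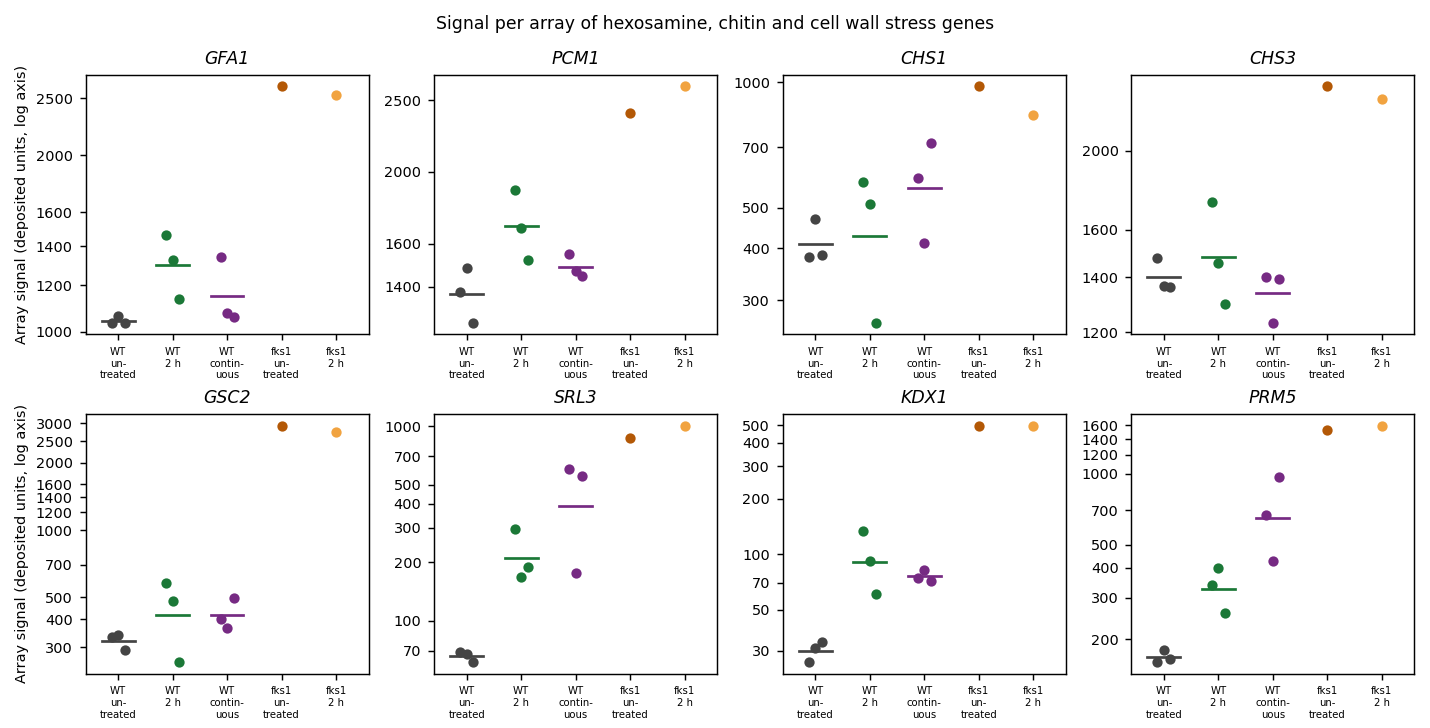
Signal on each array (deposited units, log axis) of 4 hexosamine and chitin genes (GFA1, PCM1, CHS1, CHS3), GSC2, and 3 cell wall stress genes (SRL3, KDX1, PRM5), with 3 wild-type arrays per condition, 1 fks1 array per condition, and lines at the geometric mean of 3 arrays. KDX1 measured 26.1 to 33.3 in untreated wild type, 61.2 to 133.6 after 2 h and 496.5 in untreated fks1 cells; the 2 h difference of CHS1 and CHS3 changed sign when 2 h array 1 was left out, and that of GSC2 between continuous and 2 h changed sign under median or quantile scaling.

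In continuous glucosamine 124 probe sets passed, 91 higher and 33 lower, and 40 named genes were among them. Family probe sets were 77 of the 124 and 75 of the 91 rises, so the excess of rises rests on them. Continuous arrays did not go together with untreated or 2 h arrays of the same number. Any batch of their own, which the labels do not give, could not be told apart from the continuous treatment, here or against 2 h. HPF1, the gene of an abundant cell wall mannoprotein, fell 3.24-fold, from 6331 ± 546 to 1951 ± 124 (SD, n = 3; adjusted p = 0.00019 by limma). HSP12, a small stress protein gene, fell 11.1-fold (log2 -3.47, SE 0.66, adjusted p = 0.0408), from untreated signals that ran from 889.6 to 4015.1. It passed in 12 of 27 alternatives, with log2 -4.07 to -2.90. INH1, the inhibitor of the mitochondrial ATP synthase, fell too (-3.17, SE 0.50). MET17, the O-acetylhomoserine sulfhydrylase (-2.81, SE 0.46), and PHO5 (-2.40, SE 0.41) fell as well. BY4741 lacks MET17 by its textbook genotype, so whether the fall of MET17 is a response to glucosamine is open. SRL3 rose 5.94-fold (log2 2.57, SE 0.42) and PRM5 3.88-fold (1.96, SE 0.28). IME1, the master regulator of meiosis, rose 2.84-fold (1.51, SE 0.21) and ATF1, the alcohol acetyltransferase, 2.65-fold (1.41, SE 0.25). ANB1 and AAC3, the translation factor and ADP/ATP carrier genes of cells without oxygen, rose by log2 1.39 (SE 0.27) and 1.24 (SE 0.21). RIB4 rose by log2 0.87 (SE 0.10, adjusted p = 0.0117).

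Energy and nutrient genes were among the falls. All 33 genes of the respiratory chain had a negative log2 difference (median -0.79, camera adjusted p = 6.85e-18), 3 fell over all probe sets and 17 adjusted over the list alone. The 3 were CYC1, cytochrome c (-1.69, SE 0.33, adjusted p = 0.0421), COX4 (-1.46, SE 0.25, adjusted p = 0.0289) and QCR6 (-1.04, SE 0.16, adjusted p = 0.0272). The list's call was lost with an estimated correlation (adjusted p = 0.374), as were those of the other lists of this paragraph, at the same adjusted p of 0.374 except for general stress (0.695), and fry called 0 of the 26 lists (smallest adjusted p = 0.0686). Of the 16 TCA cycle genes 15 were negative (median -0.85, adjusted p = 3.78e-08). None passed over all probe sets, 10 fell adjusted over the list alone, SDH1 (-1.55) and ACO1 (-1.41) among them, and CIT2 rose (0.96). All 16 phosphate genes were negative (median -0.72, adjusted p = 2.83e-10), with PHO5 and PHM6 (-2.14, SE 0.43) past over all probe sets and 12 adjusted over the list alone. The 28 general stress genes had a median of -0.48 (23 negative, adjusted p = 0.000177), and HSP12 was the 1 that fell by either adjustment. On the continuous arrays the mean of that list was -0.92, -1.21 and 0.25 relative to untreated cells, so array 3 stood apart and the call was lost without array 2 (adjusted p = 0.115), while the respiratory mean ran from -0.9996 to -0.56. The untreated arrays themselves spread from -0.40 to 0.22 in the respiratory mean and from -0.54 to 0.48 in the stress mean. Hexose transport (10 of 12 negative, median -0.56, adjusted p = 0.00184) had HXT2, HXT6 and HXT7 past adjusted over the list alone, and the methionine and sulfur list (19 of 23, median -0.22, adjusted p = 0.000934) had 0.

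**Figure D2:**
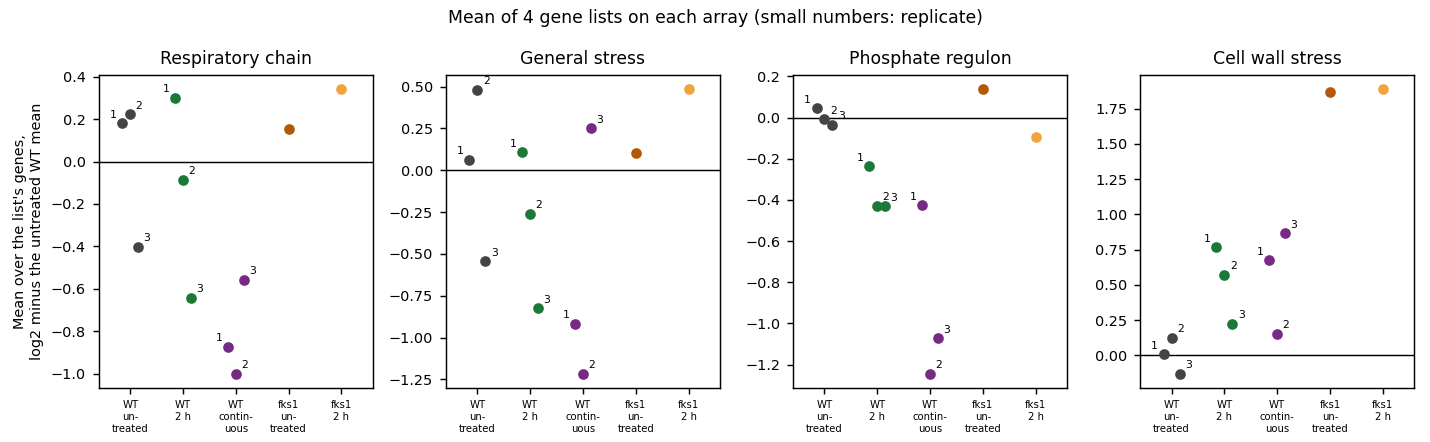
Mean over the tested genes of 4 lists on each array, in log2 units relative to the mean of the 3 untreated wild-type arrays, with replicate numbers beside the wild-type points. The respiratory mean is -0.9996 to -0.56 on the continuous arrays and -0.40 on untreated array 3, and the cell wall stress mean is 1.87 on the untreated fks1 array.

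Cell wall stress and mating lists were among those that camera called in continuous glucosamine, while the mannoprotein list did not pass (camera adjusted p = 0.136). Of 24 cell wall stress genes 17 were positive (median 0.38, camera adjusted p = 0.000727, adjusted p = 0.654 with an estimated correlation). Its means on the continuous arrays were 0.67, 0.15 and 0.86, array 2 close to untreated array 2 (0.12), and SRL3 read 605.2, 176 and 554.6 on them. SRL3 and PRM5 rose over all probe sets, and adjusted over the list alone 8 rose and 1 fell. The 8 included SLT2, the kinase of the cell integrity pathway (1.51), its relative KDX1 (1.34) and the transcription factor gene RLM1 (1.08), and the 1 that fell was the mannoprotein gene CWP1 (-0.52). The hexosamine and chitin list did not pass (8 of 12 positive, median 0.05, adjusted p = 0.896), and 0 of its members passed by limma over all probe sets or adjusted over the list alone, while 1 had an unadjusted p under 0.05. That was BNI4, which anchors chitin synthesis at the bud neck, at -0.58 (SE 0.16, adjusted p = 0.101). Glucan synthesis (17 of 24 negative, median -0.13, adjusted p = 0.0465) and protein glycosylation (32 of 34, median -0.21, adjusted p = 4.59e-07) were lower with 0 members past by either adjustment, as was heat shock (16 of 18, median -0.21, adjusted p = 0.0167). Their adjusted p with an estimated correlation were 0.654, 0.374 and 0.720. Mating type a and pheromone genes were higher (17 of 18, median 0.49, adjusted p = 8.42e-07, adjusted p = 0.374 with an estimated correlation). The untreated arrays ran from -0.32 to 0.24 in the mean of that list and the continuous ones from 0.34 to 0.68. ASG7 rose over all probe sets (1.09, SE 0.22, adjusted p = 0.0482), and 6 rose adjusted over the list alone, among them FUS3 (0.99) and SST2 (0.95). Ribosome biogenesis was higher (43 of 50, median 0.16, adjusted p = 0.00940, adjusted p = 0.885 with an estimated correlation), with 0 members past by either adjustment. Its means on the continuous arrays were 0.44, 0.31 and -0.19, array 3 below every untreated array (-0.17 to 0.10). Without untreated array 1 or continuous array 1 or 2 that call was lost (adjusted p = 0.138, 0.777 and 0.126). The glucan call was lost without untreated array 1, 2 h array 2 or 3 or continuous array 1 or 2, and the heat shock call without untreated array 1 or 3 or continuous array 1 or 2.

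Of the further calls, YSF3, JEN1 and YHR212W-A lay near the floor of the arrays in the lower group. YSF3 rose from 3 untreated arrays at the floor to 20.1 ± 3.71 (SD, n = 3), which is under the control percentile of 25.5. JEN1, the lactate transporter gene, fell from 28.2 ± 7.20 to the floor on all 3 continuous arrays. YHR212W-A fell from a mean of 43.9 to 12.3, under the control percentile. Its log2 difference of -1.99 ran from -2.46 to -0.78 over the alternatives. With group means above that percentile, SRD1 (1.16) and SSK22 (0.95) rose, and YDR034C-A (-2.08) and the U6 RNA gene SNR6 (-1.96) fell. The YDR034C-A call rests on 1 of 7 probe sets, and the other 6 did not pass (-0.74 to 0.24). Of the 91 rises 75 were family probe sets that bind transcripts of related genes, mostly without a gene name, and 12 probe sets passed once all family probe sets were left out. The median of these 75 was 0.89 in continuous glucosamine and 0.72 on the untreated fks1 array. The count of 124 was 16 without untreated array 1, 2 without untreated array 2, 5 without untreated array 3, 68 without 2 h array 2, 12 without continuous array 1 and 26 without continuous array 2. HPF1 passed under all 27 alternatives, but MET17 under 16, CYC1 under 14, ANB1 under 13 and PHM6 under 12 of 27, ASG7 under 8 of 26, YSF3 under 8 of 24 and JEN1 under 6 of 25. By limma 1193 probe sets had an unadjusted p under 0.05, against 430.8 by chance, and the arrays of both groups did not overlap for 20.1% of the probe sets, where chance gives 10%.

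**Figure D3:**
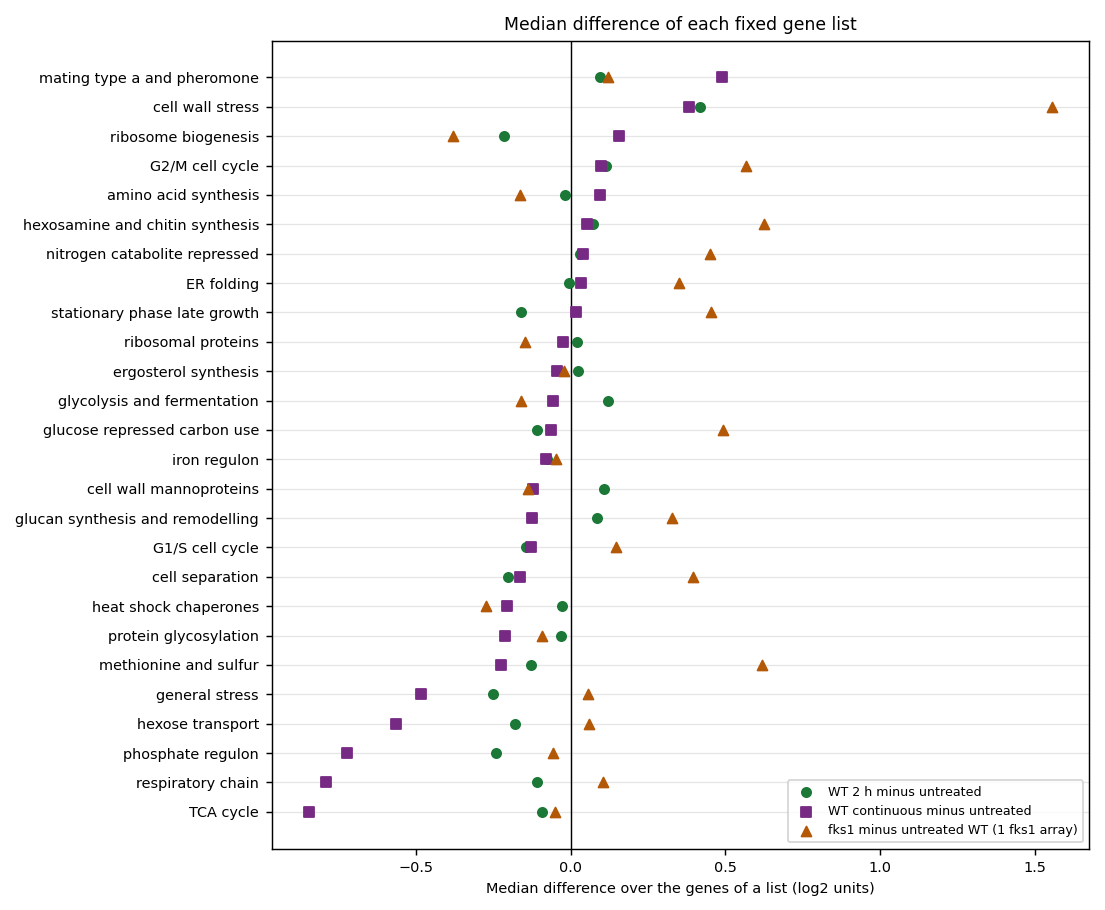
Median log2 difference over the tested genes of each of 26 lists (horizontal axis, log2 units) for wild type after 2 h of glucosamine (circles) and in continuous glucosamine (squares), each of 3 arrays against 3 untreated, and for the 1 untreated fks1 array (triangles). The cell wall stress median is 0.42, 0.38 and 1.56 in these; the ribosomal protein list changed its direction under quantile scaling in continuous against 2 h glucosamine, a comparison not drawn here.

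Continuous and 2 h glucosamine differed directly in 5 probe sets. ARO10 and ARO9, the decarboxylase and aminotransferase of aromatic amino acid breakdown, were lower in continuous glucosamine by -2.02 (SE 0.18, adjusted p = 0.00283) and -1.67 (SE 0.18, adjusted p = 0.00747), with signals of 129 ± 17.5 against 524 ± 97.2 and 463 ± 96.9 against 1459 ± 111 (SD, n = 3). HPF1 was lower (-1.06, SE 0.11, adjusted p = 0.00747), as was a probe set shared by several genes (-1.44), and AAC3 was higher (1.57, SE 0.21, adjusted p = 0.0331). Against untreated cells ARO10 (log2 -1.64) and ARO9 (-1.04) fell in continuous glucosamine, while their 2 h differences of 0.38 and 0.63 did not pass. By camera 2 lists were higher and 13 lower in continuous than in 2 h glucosamine. The respiratory chain (33 of 33 negative, median -0.62, adjusted p = 1.56e-17, 14 adjusted over the list alone) and the TCA cycle (15 of 16, median -0.62, 7 adjusted over the list alone) were among the lower and ribosome biogenesis (49 of 50 positive, median 0.40, adjusted p = 2.2e-06, 0 adjusted over the list alone) among the higher. All 15 were lost with an estimated correlation (smallest adjusted p = 0.357), and fry called 0 (smallest adjusted p = 0.189). The 5 calls became 2 without 2 h array 1 and 9 without continuous array 2. Median scaling moved the median of all probe sets in this comparison from 0.05 to -0.09.

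All 3 probe sets called at 2 h were also called in continuous glucosamine in the same direction, though both comparisons subtract the same untreated arrays. Across all 8616 probe sets, which are not independent replicates, the differences of the groups correlated at r = 0.437 (rho = 0.394), with a covariance of 0.0632. Simulated groups without any effect that share the untreated arrays gave r = 0.5001 (covariance 0.0509) with independent arrays and r = 0.360 (covariance 0.0265) with untreated and 2 h arrays paired as observed, so the no-change value depends on the pairing.

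In the untreated fks1 array FKS1 itself read 24.4, under the control percentile of 25.5, against 7404 ± 236 (SD, n = 3) in untreated wild type, at least 291-fold lower. Of its 7 other probe sets 3 read above that percentile in fks1, with smaller falls: 1592.1 to 64.1, 437.4 to 48.5 and 6253.9 to 39.7. Cell wall stress genes were far higher: CRG1, a methyltransferase gene, measured at least 21.7-fold (25.1 ± 7.64 in wild type, under the control percentile, and 603.3 in fks1), KDX1 16.5-fold, SRL3 13.2-fold, PRM5 9.11-fold and GSC2, the alternative glucan synthase subunit, 9.14-fold (321.5 ± 26.7 and 2930). Of the 24 genes of that list 16 lay at least 2-fold above each untreated array and 0 below, and the median was 1.56, where single wild-type arrays with glucosamine reached 0.758. Of the 12 hexosamine and chitin genes 2 passed the rule, with a list median of 0.62 where single treated wild-type arrays ran from -0.0783 to 0.198. GFA1 measured 2.51-fold (1045 ± 14.8 and 2622) and CHS1 2.39-fold. PCM1 (1.76-fold), CHS3 (1.71-fold) and CHS7, which CHS3 needs to leave the endoplasmic reticulum (1.67-fold), stayed under the rule, and GNA1 (log2 -0.07) and BNI4 (0.10) lay among the untreated arrays. With the spread pooled over all arrays GFA1 had adjusted p = 0.0179, CHS1 0.251 and CHS3 0.121, and whether the fks1 difference exceeds that of glucosamine was not tested.

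Nutrient genes differed as well. MET17 read 7.6, at the floor, against 1046 ± 314 in wild type, at least 39.6-fold lower with the control percentile as the limit, and the sulfate assimilation genes MET3 (6.33-fold), MET14 (3.98-fold) and SUL2 (3.11-fold) were higher. So was the cystathionine beta-lyase gene STR3 (3.92-fold), with 7 of 23 genes of the methionine and sulfur list by the rule and a median of 0.62, where single wild-type arrays reached 0.0783. By its textbook genotype BY4741 lacks MET17, so whether wild type and fks1 share a strain background is open, and the MET genes and other differences from fks1 stand beside that doubt. The phosphate transporter gene PHO89 measured 7.46-fold, while the phosphate list had a median of -0.06. Ribosome biogenesis genes had a median of -0.38, with 0 of 50 by the rule, while single arrays of wild type ran from -0.24 to 0.11 untreated and from -0.62 to 0.42 with glucosamine. Other large differences were YPL088W (11.5-fold), MNC1 (10.6-fold), CPP3 (10.4-fold), RTA1 (at least 5.68-fold) and PIR3 (7.84-fold) higher. SNR3 (at least 3.58-fold), MAE1, the malic enzyme (4.03-fold), YAR068W (3.99-fold), GAS2 (3.41-fold), WSC4 (3.28-fold), APE1 (3.04-fold), RPL7B (2.93-fold) and MSH1 (2.49-fold) were lower. A second RPL7B probe set went the other way, from 793.8 in wild type to 936.4. With the spread pooled over all arrays YPL088W had adjusted p = 0.00149, RTA1 0.0253, CPP3 0.0461, MNC1 0.203, PIR3 0.1496 and these 8 lower genes 0.0908 to 0.369. Those p-values assume that the 1 fks1 array varies like the wild-type ones and cannot separate the mutation from that array or culture. The rule counted 223 probe sets higher and 43 lower, a total of 266. Set against only 2 untreated arrays, without array 1, 2 or 3, fks1 gave 474, 402 and 382, and the left-out wild-type array itself gave 220, 283 and 359 against the same 2. The pooled spread gave 51 limma calls, 36 higher and 15 lower. Those 51 became 22, 30 and 20 without untreated array 1, 2 and 3, 33 without 2 h array 2 and 32 without continuous array 1.

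Within fks1 the 2 h glucosamine array read close to the untreated one for 3 cell wall genes: GFA1 measured 2538 against 2622, KDX1 493.8 against 496.5 and GSC2 2749 against 2930. Others moved further, with CRG1 (794.7 against 603.3) and SRL3 (1007.9 against 866.9) higher and SKT5 (366.4 against 490.6) and CHS5 (665.9 against 847.2) lower. The 6 other GSC2 probe sets were all higher with glucosamine, from 1785.3 to 1944.4 in the strongest and from 68.6 to 101.7 in the weakest. By the rule 0 of the 24 cell wall stress genes reached 2-fold, while 2 of the 24 glucan genes were lower, FKS1 and SCW10 (5597 and 2489). The cell separation list had a median of -0.29 (wild-type pairs -0.33 to -0.11) and the mannoprotein list 0.17 (0.0220 to 0.0881). RIB4 measured 3173 against 1687, and the stress gene DDR2 4950 against 2048. RRP14, a ribosome biogenesis gene, was 3.83-fold lower (342.2 and 89.4). The ribosome biogenesis list had a median of -0.55, the general stress list 0.40, the TCA cycle list 0.24 and the respiratory chain list 0.23, all among the outermost of the 10000 random lists. Random lists leave out the correlation within a list, and the wild-type pairs of the same number ran from -0.476 to -0.0064, -0.784 to 0.12, -0.250 to 0.157 and -0.289 to 0.149 in these lists, so each fks1 median lay outside the 3 pairs. Single untreated wild-type arrays against the others ran from -0.236 to 0.111, -0.752 to 0.744, -0.457 to 0.285 and -0.551 to 0.295 in the same lists. The general stress, TCA cycle and respiratory medians of fks1 lay inside these ranges. Whether the fks1 arrays go together as the wild-type pairs do cannot be seen from 1 array each. The mating type a and pheromone list, with a median of 0.21, stood as far out among the random lists as the TCA cycle list. It lay outside its wild-type pairs (-0.0383 to 0.169) and inside the range of single untreated arrays (-0.429 to 0.426). The 2-fold rule gave 115 probe sets higher and 222 lower, while the wild-type pairs of the same number gave 455, 394 and 688, all above the total of 337. Other large differences (CRC1, DOG1, GIT1, YOL164W-A, SUF16, YPR015C, YOL024W, YNL194C, TOP3, MPH2, AQY1, HSH49, YIG1, POL30) mostly lay near the floor. Across probe sets, which are not independent replicates, the 2 h responses of the strains correlated at r = 0.0464 (rho = 0.0529), which was -0.0437 without 2 h array 1 and 0.103 without 2 h array 3. The 1 probe set that limma called for a difference of the responses was FKS1 (-1.80, adjusted p = 0.0334), but both fks1 signals of that probe set were under the control percentile, and 201 had an unadjusted p under 0.05. Leaving out any of the 9 wild-type arrays gave 0 such calls.

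The differences of fks1 from untreated wild type correlated with those of 2 h glucosamine at r = 0.323 (rho = 0.340) and with those of continuous glucosamine at r = 0.310 (rho = 0.326) across probe sets. Simulated groups without effects, which share the untreated arrays, gave 0.354 and 0.352 with independent arrays, and the first was 0.256 with untreated and 2 h arrays paired. With the untreated arrays split between the comparisons r lay between -0.0520 and 0.144. The covariances were 0.0652 and 0.0807 against simulated ones of 0.0510 (0.0266 paired) and 0.0507. Without 2 h array 1 the first r was 0.209.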

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

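The comparisons of groups and strains and the splits of the arrays in this part were set before the data were examined, while the list tests of the difference between the strains and the tests of explanations for MET17, the respiratory chain and the family probe sets were chosen only after the result was seen. A direct test of continuous against 2 h glucosamine singled out ARO10 (log2 -2.02), ARO9 (-1.67), a probe set shared by several genes (-1.44), HPF1 (-1.06) and AAC3 (1.57). By camera at the preset correlation the same comparison singled out lower list medians for hexose transport (-0.63), respiratory chain (-0.62), TCA cycle (-0.62), phosphate (-0.49), general stress (-0.25), glycosylation (-0.23), glucan (-0.21), glycolysis (-0.18), mannoproteins (-0.18), cell wall stress (-0.15), methionine and sulfur (-0.14), heat shock (-0.13) and ribosomal proteins (-0.0391). It also singled out higher medians for ribosome biogenesis (0.40) and mating type a (0.35). None of these 15 lists passed with an estimated correlation (smallest adjusted p = 0.357).

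FKS1 was called for a difference of the 2 h responses of fks1 and wild type (-1.80), but both fks1 signals of that probe set lie under the control percentile of 25.5 and the call is lost when any wild-type array is left out. In the FKS1 probe sets that read above it on both fks1 arrays the signals without and with glucosamine were 48.5 and 43.5, and 64.1 and 64.3. Lists that camera singled out for the difference of the responses were general stress (0.70), respiratory chain (0.36), TCA cycle (0.34), cell wall stress (-0.49), G2/M (-0.32) and ribosome biogenesis (-0.30), and 0 of these 6 passed with an estimated correlation (smallest adjusted p = 0.977). The fks1 response is 1 array against 1 and the fit leaves out the pairing of the wild-type arrays, so these values cannot separate the strains from single arrays. In data outside the comparisons, a control probe set for 25S rRNA read 11615.4 on 2 h array 3, 20.4 on untreated array 2 and 128.7 on 2 h array 2. Probe sets left untested because wild-type arrays lay at the floor read 68.6 (GSC2), 37.1 (YPR078C) and 85.9 (BAG7) in fks1, above the control percentile of 25.5. With glucosamine these were 101.7, 36.5 and 87.1, and BAG7 also read 43.4 and 30.5 on continuous arrays 1 and 3.

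MET17 is deleted in the textbook genotype of BY4741, and the labels give no genotype beyond the strain name, yet it read 684.1 to 1248.1 in untreated cells, 265.3 to 985.3 after 2 h and 108.5 to 223 in continuous glucosamine. Of the other marker genes URA3 read at most 6.7 on every array, while HIS3 read 731 ± 81.6 and LEU2 74.6 ± 14.9 in untreated wild type (SD, n = 3) and 479.5 and 65.8 in fks1. LYS2, which is not among the marker genes of the strain, read at least 502.7 on every array. The LEU2 values come from its brightest probe set. The other LEU2 probe sets averaged 19.3 and 24 in untreated wild type and read 23.1 and 12.3 in untreated fks1. These lie under the control percentile of 25.5, while with glucosamine they read 31.7 and 15.4 in fks1. Such signals cannot tell whether HIS3 or LEU2 is intact. HIS3 and LYS2 gave signal in both strains, unlike MET17. Cross-hybridisation of the probe set does not account for the MET17 signal, since the highest fks1 signal was 7.7 under a control percentile of 25.5, and RNA from alpha cells does not either, since 4 alpha markers had a median of -0.27 (-1.10 to 0.08) in wild type relative to fks1. The sulfur genes fell together by a median of -0.22 over 23 genes (SD 0.44), a smaller fall than that of MET17 (-2.81). Of the 23, 19 were negative (camera adjusted p = 0.000934, and 0.374 with an estimated correlation). A median cannot exclude a shared fall that was stronger in MET17. Several explanations could not be told apart. They are a wild type other than BY4741 or of another background than fks1, and a culture that mixes cells with and without MET17. An effect of glucosamine on MET17, alone or with the other sulfur genes, is another. A mixture that differed between groups would bear on the other wild-type comparisons too. The higher sulfur genes in fks1 stand beside the MET17 difference between the strains.

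The fall of the respiratory chain genes in continuous glucosamine was weighed against growth stage, RNA quality and oxygen. With the mean of the general stress genes as a covariate over the 9 arrays, the difference went from -0.81 (SE 0.30) to -0.48 (SE 0.19) and so stayed negative. That mean is an imprecise measure of growth stage and may itself change with glucosamine. A remainder can be left even where growth stage explains the whole fall, so the covariate cannot tell how much of it growth stage explains. The ACT1 3' to 5' ratio differed by -0.0387 between continuous and untreated arrays (1.32 ± 0.0457 and 1.36 ± 0.0847, SD, n = 3), which gives no sign of poorer RNA. ANB1 and AAC3 rose as in cells without oxygen. A list of 16 oxygen and heme genes, chosen without them, had a median of 0.0015, 8 positive and 8 negative. Limma called 0 of the 16, and camera gave p = 0.472 (p = 0.470 with an estimated correlation). UPC2 (0.92) and HEM13 (0.90) lay highest, and COX5B (-0.99) and CYC7 (-0.83) lowest. CYC7 is also a member of the respiratory list whose fall was weighed here. The list test cannot tell whether oxygen or heme had a part.

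The 75 family probe sets among the rises of continuous glucosamine had a mean residual correlation of 0.507. That lay above the highest of 1000 random sets of the other 463 family probe sets (0.285), so the 75 did not vary independently. Distinct genes can vary together as much: camera's estimated correlation was 0.773 in the respiratory chain list and 0.733 in ribosome biogenesis. The value therefore cannot tell a few shared transcripts from many that vary together. The count of 124 cannot be read as the number of genes that changed. Of the 75, 54 had no gene name, 16 matched several genes and 5 matched 1 gene, 3 of these YGR109W-B, a transposon gene. Scaling was tested with the smallest median rise over the scalings, 0.84 against 0.89 as deposited, so the scalings tried do not account for them. Median scaling moved the median of all probe sets in this comparison only from 0.02 to -0.03. The test therefore cannot exclude an array effect on this class of probe sets alone. All 538 tested family probe sets had a median of 0.45 against 0.0070 for the others. The 75 had a median of 0.33 at 2 h and of 0.72 on the untreated fks1 array, which had no glucosamine. Each of these differences subtracts the same untreated wild-type arrays. A rise in continuous glucosamine therefore cannot be told apart from low values on those arrays. No biological explanation was tested.

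The arrays of each pair of groups can be split in 10 ways, too few for a share under 0.05. The real 2 h grouping gave 3 calls and the highest other split 4, while among the 4 splits that part all 3 number pairs the highest other gave 0. Continuous against untreated gave 124 calls and the highest other 0, and continuous against 2 h gave 5 and 0. For the preset gene lists the real counts of 10, 12 and 15 stand beside highest others of 9, 11 and 13, so nearly as many list calls came from other splits. Among the 2 h splits that part all number pairs the highest other was 5 lists. The absolute median of the cell wall stress genes at 2 h was 0.417 with a highest other of 0.398, that of the respiratory chain in continuous glucosamine 0.790 with 0.619, and that of the phosphate genes 0.722 with 0.614. For the cell wall stress genes at 2 h, the highest other among the splits that part all number pairs was 0.2515. In continuous against 2 h the highest other lay above the real value for the respiratory chain (0.707 and 0.618), the phosphate genes (0.520 and 0.490) and the cell wall stress genes (0.420 and 0.147).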

How the results depend on the processing

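Alternatives on the control floor, a mean signal of 100, family probe sets, unnamed and shared probe sets, the untreated and 2 h arrays numbered 2 and the paired 6 arrays were chosen only after the result was seen. Between 76.7% and 81.3% of signals per array exceeded the control percentile, and 8.40% to 11.6% lay at the floor, which limits what low signals such as FKS1 in fks1 or JEN1 can show. Where an array was left out, the fit pooled the spread over groups. HPF1 (continuous) and ARO10 (continuous against 2 h) passed under all 27 alternatives, and no called gene reversed. Where no cause is named, the cause was not tested.

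The 3 calls at 2 h were 1 under quantile normalization, a floor at 0.5 or 2 times, log2 of value plus floor, a mean log2 filter and the control floor. They were 0 with 1 probe set per gene, without unnamed and shared probe sets, with only the 2 groups compared, with a replicate block over 9 arrays and without the arrays numbered 2, and 0 to 1 with 1 array left out. The paired block of 6 arrays gave 17. Continuous against untreated (124) gave 16 with no filter, 7 with 1 probe set per gene, 12 without family probe sets, 5 without unnamed and shared ones, 11 with eBayes without the trend, 3 without the arrays numbered 2 and 2 to 182 with 1 array left out. Its replicate block gave 50 calls, 46 of them among the 124, though same-numbered untreated and continuous arrays did not correlate best with each other, a hint from the data and not the design. Continuous against 2 h (5) gave 3 without the arrays numbered 2 and 2 to 9 with 1 array left out.

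With the inter-gene correlation estimated, 0 lists passed at 2 h, 0 in continuous glucosamine and 0 in continuous against 2 h, and with 1 array left out the 2 h lists numbered 5 to 11. The 9-array block added mannoproteins at 2 h (adjusted p = 0.0441), and the block changed no other call beyond those given beside the 2 h results. Reversed were ribosome biogenesis at 2 h without 2 h array 1 (adjusted p = 0.185, and 3.54e-07, lower, without 2 h array 3), and in continuous against 2 h cell wall stress without continuous array 2 (0.648) and ribosomal proteins under quantile normalization (0.0332), whose median is only -0.0391 as deposited.

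The 266 probe sets of fks1 by the 2-fold rule were 153 with 1 probe set per gene, 117 at a mean signal of 100 or more, 73 at 3-fold and 382 to 474 with 1 array left out. With the pooled spread (51) there were 159 with no filter, 8 without the arrays numbered 2 and 20 to 51 with 1 array left out. Glucosamine in fks1 (337) gave 523 with the floor at 0.5 times, 179 at 2 times, 220 with log2 of value plus floor, 202 with a mean log2 filter, 95 with 1 probe set per gene, 105 with the control floor, 51 at a mean signal of 100 or more and 77 at 3-fold. The difference of the 2 h responses (1) gave 61 calls with no filter, and 0 under median or quantile scaling, the floor at 2 times, log2 of value plus floor, the control floor, eBayes without the trend, without the arrays numbered 2 and with any 1 array left out. The r of the fks1 and wild-type 2 h responses (0.0464) was 0.110 at a mean signal of 100 or more, 0.0916 without the arrays numbered 2 and -0.0437 to 0.103 with 1 array left out. With 1 array left out the other r ranged from 0.302 to 0.559 (2 h and continuous), 0.209 to 0.466 (2 h and fks1) and 0.240 to 0.422 (continuous and fks1, 0.367 without the arrays numbered 2).

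Of 5163 values of uncalled named genes, 24 passed under an alternative and 37 reversed, none of them with a call. With 1 array left out, the 2 h differences ranged from -0.115 to 0.411 (CNE1), -0.76 to 0.0226 (MET2), -0.0923 to 0.611 (ERG12), -1.99 to 0.0046 (HSP30), -0.141 to 0.0866 (GNA1), -0.156 to 0.406 (CHS1), -0.0289 to 0.178 (CHS3), -0.252 to 0.183 (SKT5) and -0.123 to 0.251 (HIS3). Those of continuous glucosamine ranged from -0.0159 to 0.688 (ERG12), -0.196 to 0.319 (STE3), -0.0089 to 0.109 (QRI1), -0.0692 to 0.108 (CHS5) and -0.106 to 0.0893 (CHS6). Those of continuous against 2 h ranged from -0.338 to 0.247 (GSC2) and -0.139 to 0.235 (HIS3). Under median and quantile scaling the 2 h difference of GNA1 was 0.0638 and 0.0420 and that of QRI1 0.0605 and 0.0627. In continuous glucosamine CHS6 was -0.0519 and -0.0462 under these, and CHS5 -0.0128 under median scaling. In continuous against 2 h GSC2 was -0.137 and -0.0711, QRI1 -0.0464 and -0.0068, and HIS3 -0.0447 under median scaling. Without the untreated and 2 h arrays numbered 2, QRI1 was 0.0026 and HIS3 -0.0391 at 2 h.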

Other observations

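Genes named in no comparison above also passed in continuous glucosamine or over a list alone. Within the respiratory list RIP1, the iron-sulfur subunit of the cytochrome bc1 complex (-1.55), NDE1, an external NADH dehydrogenase (-1.24), and ATP2, a subunit of the ATP synthase (-0.95), fell adjusted over the list alone, and within the phosphate list SPL2 (-1.95) and PHO84, the high-affinity phosphate transporter (-0.59), did so. In the iron list FET3, the multicopper oxidase (-0.99), and FRE1, a ferric reductase (-1.36), fell adjusted over the list alone. FLO11, a cell surface flocculin gene, fell too (-0.61), and the mannoprotein gene DAN1 rose (0.77), both adjusted over the list alone. These genes were chosen after their values were seen.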
